A study of Gallus gallus with 14 samples.

How the data were processed

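Total RNA from 14 chicken retinas was sequenced, 7 from control eyes and 7 from eyes that had worn a lens of -10 dioptres for 1 day. The birds were White Leghorn chickens, a layer breed, aged 3 days when lenses were fitted, and each library was made after depletion of ribosomal RNA with a stranded kit, per the labels' protocols. The labels do not describe how control eyes were handled, do not give the sex of the birds and do not say whether the retinas came from separate birds. The p-values below therefore measure the spread between these samples, which may partly be technical.

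The submitters' processing notes name STAR, Partek and the genome build GRCg6a, with no role, order or version. How reads were assigned to genes, and whether strand was used in that step, is not given in the sources used here, so overlapping genes and close paralogs may share reads. The deposited table holds 1 column per library and 18631 rows with gene symbols, and the authors' values were read as CPM (counts scaled to a total of 1000000 reads) from the values themselves: the low values of each library, less a constant of 0.0001 that stands in every cell, were mostly whole multiples of 1 step that was the same for every gene. Within a tolerance of 0.05 steps, 93.2% to 94.5% of the values up to 20 steps were whole. That share was too low to treat the values as read counts, so no count model was fitted. The step gave a read total behind the CPM values of 27.7 to 49.3 M reads per library (median 37.4), and that 8.65 to 15.3 M reads fell on the listed genes, so that 1 read was worth 0.0203 to 0.0361 CPM. The values were not divided by gene length. The columns summed to 298680 to 319250, or 29.9% to 31.9% of that total, so the total covered more reads than those on the listed genes. The table held 0 columns of other series. Chromosome names were assigned to the sequences of the table by the RefSeq names of their genes (15419 symbols matched a table of the GRCg7b assembly, used for names only); coordinates are those of the deposited table, on GRCg6a.

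Deposited values were taken as log2(CPM + 1), and 11005 genes with a mean of at least 1 CPM over the 14 libraries were tested; 7626 fell under this filter. Fold changes are on the log2(CPM + 1) scale, which understates the change of low genes. Lens and control libraries were compared with limma 3.58.1 in R 4.3.3 (a linear model with a mean-variance trend, two-sided, Benjamini-Hochberg adjustment, adjusted p under 0.05). From 38 gene lists for retinal signalling systems, retinal cell types, tissues that a dissection can carry along, general pathways and W-linked genes, 35 had at least 5 tested members and entered fry, which tests whether a list moves on balance in 1 direction, and, as fry's mixed test, whether its genes change in either direction. Camera, with a correlation of 0.01 and with an estimated one, was run beside them. Lists of red blood cell, microglia and leukocyte, and mitochondrially encoded genes had 2, 4 and 0 tested members and were not tested. A further 25 genes often measured in the chick retina under defocus were fixed as a group. The tests, lists, filter, pseudocount and most alternatives were chosen before the data were examined.

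The titles number the lens libraries 1 to 4 and 12 to 14, and the control libraries 10, 17 to 19 and 21 to 23. Each lens set against all 7 controls was a planned comparison, and the 2 lens sets were also compared with each other. Genes were named by a fixed rule: among genes past the threshold with a symbol and a mean in the upper 75%, the 10 with the largest change in each direction; of the 25 fixed genes, those past the threshold or the 3 of smallest p; for each list past its test or with 3 or more called genes, its 2 to 4 members of smallest p; and where fewer than 10 genes passed, the 10 of smallest p. Any other gene named was chosen after its values were seen: ARNTL, DRD4, EGR1, HSP90AB1, RXRA, DHRS3, RBP4, KCNV2, GUCA1C, DIO2, COL6A1 and ID4, and, under the filter, FOS, VIP and TH.

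Alternatives covered the pseudocount, the filter, 3 other scalings (median of ratios, trimmed mean of M values, quantiles), robust variance, library weights, rank-sum tests, the title letter or the mean W-linked level as a covariate, the sex chromosomes left out, and each library left out in turn. The gene test and the list tests were run on simulated data first. In simulations of 11005 genes with 200 changed, the lens against control design recovered 34% of genes changed by 1.25-fold, 82% at 1.5-fold and 96% at 2-fold, with 5 false calls. The design of lens libraries 1 to 4 against control recovered 66% at 1.5-fold, and that of lens libraries 12 to 14 against control 74%. The simulated genes varied independently, and 50 were changed 2-fold and 50 changed 3-fold, which eases the adjusted threshold. These shares need not hold for the data, where ARNTL, at 1.54-fold over all lens libraries, did not pass (limma, adjusted p = 0.1002). Replicate libraries were compared pairwise, and the closest pair, controls 19 and 23, differed by 3.14 times counting noise. Repeat libraries of 1 retina would also differ by more than counting noise, so this does not show whether any library is a repeat, and each was counted as a separate sample. Figures were drawn with matplotlib 3.10.9.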

Results

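RNA sequencing compared retinas of 7 control eyes with retinas of 7 eyes fitted with a -10 dioptre lens, which moves the image behind the retina and makes the growing chick eye elongate. The lens had been worn for 1 day, so the comparison addresses the early retinal response to such a lens. The read total behind the CPM values was 27.7 to 40.3 M reads (M, 1000000) in control libraries, 34.1 to 43.5 M in lens libraries 1 to 4 and 40.4 to 49.3 M in lens libraries 12 to 14. Values are CPM (counts scaled to a total of 1000000 reads) as deposited, given as mean ± SD over libraries.

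Over all 14 libraries, the circadian repressor PER2 had 245 ± 20.5 CPM in control retinas and 182 ± 25.4 CPM in lens retinas (n = 7 each), a log2 fold change of -0.43 (SE 0.081), and all 7 lens libraries lay below the control median. NFIL3, a transcriptional repressor with a daily rhythm, stood at 18 ± 2.14 and 25.5 ± 3.58 CPM, with 7 of 7 lens libraries above the control median. The collagen chain gene COL9A3 was at 5.30 ± 1.06 and 8.57 ± 1.18 CPM and REEP2, which shapes the endoplasmic reticulum, at 82.7 ± 7.70 and 105 ± 7.45 CPM, both higher in 7 of 7. The metabotropic glutamate receptor gene GRM5 (log2 fold change -0.34), the caspase inhibitor XIAP (-0.32), the signalling adaptor SHC4 (-0.33) and SORBS2 (-0.31) were lower in 7 of 7. None of these passed the threshold: limma called 0 genes at an adjusted p under 0.05, these 8 genes shared an adjusted p of 0.0772, and so did the uncharacterised LOC112532100 (-0.40) and LOC101751380 (0.90). At an unadjusted p under 0.05 there were 1619 genes, where 550 would be expected by chance for independent genes. Of 100 ways to split the 14 libraries into 7 and 7, the real one included, 7 gave as many, so chance is not excluded. Exact rank-sum tests called 0. PER2 lies on chromosome 9 of GRCg6a, 5654602 to 5695660 on the minus strand, as listed in the deposited table.

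Of the 25 fixed genes, 17 were tested and 8, among them FOS, VIP and TH, lay under the filter. Over all genes 0 of them passed, while 5 passed when adjusted over the list alone. PER2 had an adjusted p of 0.000863 over the list, the growth factor gene IGF1 0.0429 (log2 fold change -0.31), the nitric oxide synthase gene NOS1 0.0448 (0.41), the glucagon gene GCG 0.0448 (-0.25) and the retinoic acid receptor gene RARB 0.0497 (-0.21). GCG averaged 15.0 ± 2.49 CPM in control and 12.3 ± 0.841 CPM in lens retinas. The dopamine receptor gene DRD4 averaged 28.6 ± 4.95 and 28.9 ± 2.15 CPM, and the immediate early gene EGR1 11.6 ± 4.46 and 9.92 ± 2.80 CPM, with neither past the threshold. Only the PER2 call held when any 1 of the 14 libraries was left out; IGF1 and NOS1 kept theirs in 6 and 5 of 14 such tests, GCG and RARB in 2 each. IGF1 stood at -0.49 in lens libraries 1 to 4 and -0.08 in lens libraries 12 to 14, and the sets differed (adjusted p = 0.0464).

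No gene list moved in 1 direction (0 of 35 by fry, smallest adjusted p 0.818), but 10 lists passed the mixed test, which counts changes in either direction. The clock and melatonin list (22 tested members, adjusted p = 0.000136) and the immediate early genes (18 members, adjusted p = 0.000136) had the smallest values. NFIL3 belongs to both lists, so their results are not independent. In the clock list, 3 members were higher and 5 lower when adjusted over the list alone, and none over all genes. ARNTL, the activator whose product drives PER2, averaged 16.3 ± 3.95 CPM in control and 25.4 ± 4.23 CPM in lens retinas (log2 fold change 0.62, adjusted p = 0.1002). The other 8 lists were glycolysis and hypoxia, growth factors, nitric oxide and cyclic nucleotide signalling, cone and rod phototransduction, monoamines, ganglion cell markers and ion channels (adjusted p 0.00580 to 0.0465). With a correlation of 0.01, camera placed cholesterol synthesis higher and heat shock and ribosomal protein genes lower, and with an estimated correlation it called 0 lists (smallest adjusted p = 0.934). Lens libraries 12 to 14 taken alone had median log2 fold changes of 0.020 for the heat shock and 0.036 for the ribosomal protein list.

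**Figure D1:**
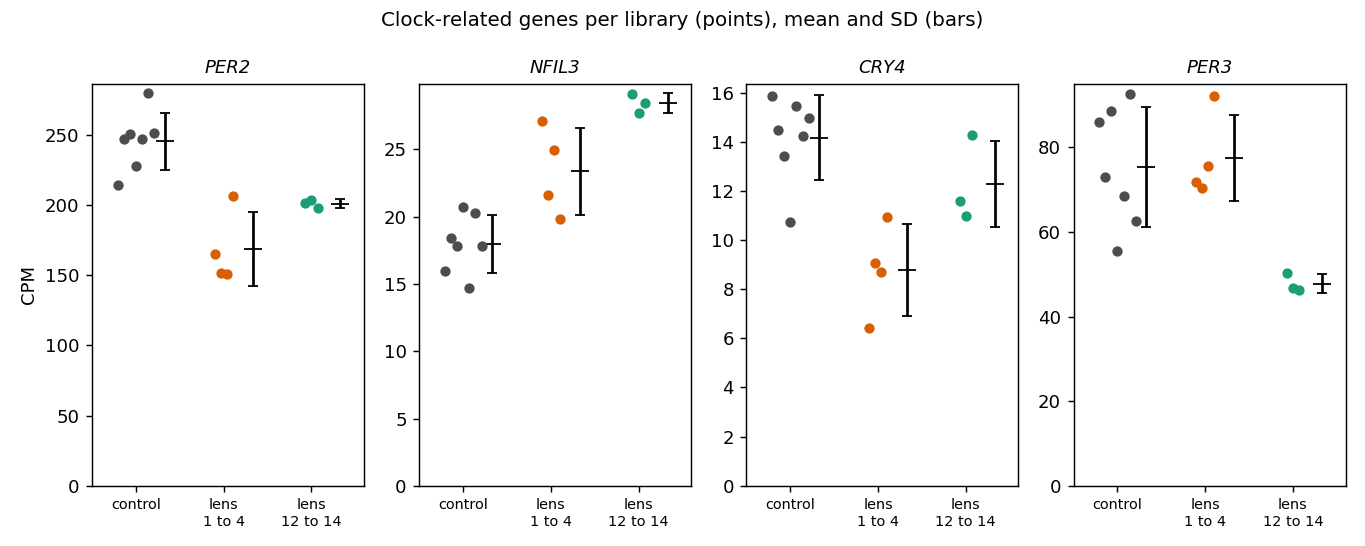
CPM of 4 clock-related genes in each library (points) of the control group (n = 7), lens libraries 1 to 4 (n = 4) and lens libraries 12 to 14 (n = 3), with mean and SD as bars on linear axes from 0. PER2 averaged 245, 169 and 201 CPM, and PER3 75.3, 77.5 and 47.8 CPM, in the 3 sets.

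The lens libraries were not alike. The first principal component (36.6% of variance) followed reads from the W chromosome, which only female birds carry. On W-linked genes, 7 libraries (3 control, 4 lens) held 604 to 655 CPM and the other 7 held 1.54 to 3.11 CPM. The 4 lens libraries with W-linked reads were 3 of libraries 1 to 4 and 1 of libraries 12 to 14, so the lens sets were not balanced for sex. The second component (17.7%) placed lens libraries 1 to 4 at 8.06 to 21.4, lens libraries 12 to 14 at -13.1 to -0.253 and controls at -13.1 to 5.26. The numbers 1 to 4 belong to lens libraries only, so a batch behind these numbers and the lens cannot be told apart within that set. Noncoding RNA genes held 5.29% to 5.84% of the CPM on listed genes in lens libraries 1 to 4, 5.52% to 6.64% in controls and 5.97% to 6.36% in lens libraries 12 to 14.

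**Figure D2:**
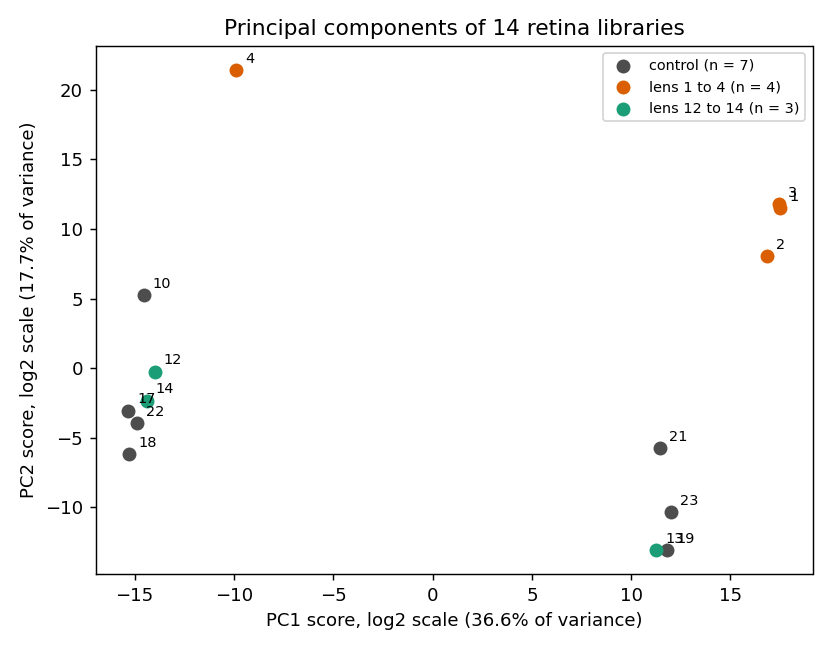
Scores of the 14 libraries on the first and second principal components of log2(CPM + 1), with the title number beside each point. Lens libraries 1 to 4 lie above all others on the second component, and control 10 is the highest control at 5.26.

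In lens libraries 1 to 4 compared with the 7 controls, several chaperone genes were among the largest falls. The cytosolic chaperone HSP90AA1 fell from 557 ± 89.4 CPM (n = 7) to 267 ± 38.0 CPM (n = 4; log2 fold change -1.05, SE 0.13, adjusted p = 0.000576), and HSPA8, DNAJA1 and HSPA2 fell by 1.03, 1.04 and 0.99 on the log2 scale. PDK4, which restrains the use of pyruvate in mitochondria, rose from 20.7 ± 4.18 to 44.4 ± 5.08 CPM (log2 fold change 1.08, adjusted p = 0.000576). The cholesterol exporter ABCA1 rose from 9.37 ± 0.980 to 16.0 ± 2.31 CPM. NEK10 showed the largest named rise, from 3.23 ± 0.887 to 11.6 ± 2.88 CPM. Limma called 1480 of 11005 genes, 1034 higher and 446 lower, with 145 of them changed by at least 1.5-fold and a median change of 0.34 on the log2 scale. The direction split depended on scaling: median-of-ratios scaling gave 678 higher of 1473 called, trimmed mean scaling 673 of 1490 and quantile scaling 770 of 1523. Leaving out lens library 1, 2 or 3 lowered the count to 869, 911 or 724, and exact rank-sum tests, which cannot give a p below 0.00606 here, called 0.

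The remaining genes with the largest rises were UBAP1L (log2 fold change 0.89), the C-type lectin CLEC3A (0.78), COCH (0.76), the transcription factor MEF2D (0.75), ACAP3 (0.71) and the stress-responsive NDRG1 (0.71). The largest fall was that of RSRP1, from 135 ± 42.3 to 54.0 ± 9.10 CPM, and other genes with large falls were the oxygen-sensing hydroxylase EGLN3 (-0.95), FBXO5 (-0.95), ARHGAP28 (-0.93), EHD4 (-0.88) and the ribosomal protein gene RPS19 (-0.82, adjusted p = 0.047). Of the fixed genes, PER2 (-0.55, adjusted p = 0.00214) and IGF1 (-0.49, adjusted p = 0.00328) fell and NOS1 rose (0.57, adjusted p = 0.0182); 7 passed when adjusted over the list alone.

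Of 29 heat shock and unfolded protein response genes, 13 fell, 1 rose and 15 did not pass, and the list fell as a whole (fry, adjusted p = 0.0265). Its test gave adjusted p = 0.756 by camera with an estimated correlation, and fry's p rose to as much as 0.106 with 1 library left out, missing the threshold without control 17, 18, 19, 21 or 23 or lens library 1, 2 or 3. HSP90B1, a chaperone of the endoplasmic reticulum, fell by 0.61 on the log2 scale. In contrast, HSP90AB1, the constitutive paralog of HSP90AA1, was the member that rose (0.48, limma, adjusted p = 0.00676). Control 10 lay between the sets here, with 374 CPM of HSP90AA1 against 214 to 300.2 CPM in lens libraries 1 to 4 and 529 to 637 CPM in the other controls. Among 26 cholesterol genes 8 rose and 0 fell, including CYP51A1 (0.44), HMGCS1 (0.45) and the sterol sensor partner INSIG1 (0.59); fry gave adjusted p = 0.115, camera 0.0134 with a correlation of 0.01 and 0.947 with an estimated correlation. Of 68 cytosolic ribosomal protein genes 4 fell (RPL12, RPL23A, RPS28 and RPS19) and 64 did not pass, and fry gave adjusted p = 0.122. Under the alternatives, fry's adjusted p ranged from 0.0352 to 0.289 for the cholesterol list and from 0.0200 to 0.289 for the ribosomal protein list.

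**Figure D3:**
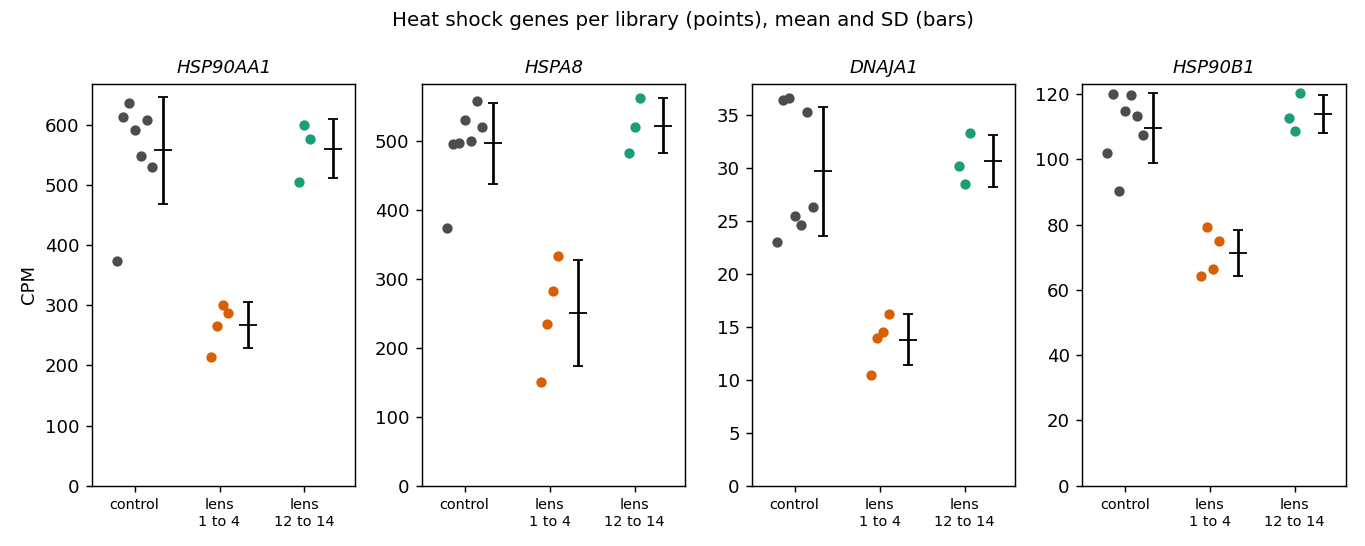
CPM of 4 heat shock genes in each library (points) of the control group (n = 7), lens libraries 1 to 4 (n = 4) and lens libraries 12 to 14 (n = 3), with mean and SD as bars on linear axes from 0. HSP90AA1 averaged 557, 267 and 561 CPM in the 3 sets, and the lowest control value was 374 CPM.

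Clock and melatonin genes changed in both directions in this set: of 22 tested, 4 rose and 5 fell (mixed test, adjusted p = 5.26e-07). ARNTL2 rose (log2 fold change 0.54, SE 0.076, adjusted p = 0.0013), CRY4, a cryptochrome, fell (-0.64), and ASMT, which makes melatonin, fell from 14.4 ± 0.982 to 11.4 ± 0.450 CPM. Among 18 immediate early genes, CSRNP1 (0.39) and NFIL3 (0.36) rose and ATF3 (-0.46) and the ERK phosphatase DUSP6 (-0.34) fell. Growth factor genes went both ways, 4 up and 5 down of 33, with IRS2, an insulin receptor substrate, higher (0.42) and SPRED1 lower (-0.39). In glycolysis and hypoxia, 4 of 30 rose and 3 fell, and P4HA1 fell by 0.47.

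Lists of neuronal cell types and transmitters also held called genes. Over all genes 1480 of 11005 were called in this comparison, and a count near that share says nothing particular about its list. The bipolar cell factor VSX1 rose from 58.1 ± 4.48 to 82.2 ± 7.89 CPM and RGS7 rose by a log2 fold change of 0.15, while GRIK1 (-0.19) and TMEM215 (-0.39) fell, giving 2 up and 2 down of 18 bipolar markers. Ganglion cell markers rose in 3 of 17, namely INA (0.37), SLC17A6 (0.26) and RBPMS2 (0.47), and POU4F1 stood at 0.22 without passing. Receptor subunits GABRA6 (-0.24), GLRA2 (-0.23) and GABRB2 (-0.19) fell, with SLC32A1 at 0.22 and not past the threshold, among 29 GABA and glycine genes. In the glutamate list 1 rose and 2 fell of 26, GRM5 by 0.40, and SLC17A8 was at -0.28 without passing. Among ion channels, KCNH5 rose (0.40) and KCNH1 (-0.53) and CACNA1D (-0.19) fell. In cyclic nucleotide signalling, PRKAR1A (0.22) and PDE9A (0.31) rose beside NOS1 and GUCY1B3 fell (-0.17). Of 27 matrix genes, AGRN rose (0.46), THBS1 (-0.56) and VCAN (-0.41) fell, and MMP16 was at -0.18 without passing. In all, 29 of 35 lists passed the mixed test, 1 passed fry in 1 direction, and camera with an estimated correlation called 0 (smallest adjusted p = 0.756). The mixed test does not set a list against the other genes, so many lists can pass it where many genes change.

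In lens libraries 12 to 14 compared with the same controls, limma called 0 genes (smallest adjusted p 0.123), with 571 at an unadjusted p under 0.05 where 550 would be expected; exact rank-sum tests called 0, but cannot give a p below 0.0167 with 3 against 7 libraries and so could hardly pass. The genes of smallest p were led by NFIL3, at 28.4 ± 0.731 CPM (n = 3) against 18 ± 2.14 CPM in control (n = 7; log2 fold change 0.64, SE 0.093). The clock genes PER3 (-0.62, adjusted p = 0.922) and PER2 (-0.28, adjusted p = 0.922) stood among the 10 of smallest p, with 47.8 ± 2.25 and 201 ± 3.03 CPM. The others were the phosphodiesterase PDE10A (-0.23) and LOC112532219 (-0.51), whose listed span lies inside that of PDE10A so that reads may be shared, LOC112532100 (-0.48), DIS3L (0.58), the tRNA-maturing TRNT1 (0.30), LOC101749752 (-0.51) and LRTM2 (-0.33). Of the fixed genes, PER2 passed when adjusted over the list alone, and GCG (-0.25), RARB (-0.14) and IGF1 (-0.08) did not. No list moved in 1 direction (fry, smallest adjusted p 0.390), and 3 passed the mixed test: the clock list (adjusted p = 0.00140), immediate early genes (adjusted p = 0.00144) and ion channels (adjusted p = 0.00144). The clock and immediate early lists share NFIL3, the gene of smallest p here. Camera with a correlation of 0.01 called 5 lists (clock, cone phototransduction, glycolysis and hypoxia, and ion channels lower, interferon response higher), and 0 with an estimated correlation (smallest adjusted p = 0.675).

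Compared directly, lens libraries 1 to 4 differed from lens libraries 12 to 14 at 551 genes, 389 higher and 162 lower, 467 of which were also called in libraries 1 to 4 against control. HSP90AA1 (267 ± 38.0 against 561 ± 49.6 CPM, adjusted p = 0.0051), DNAJA1 and HSP90B1 were lower in libraries 1 to 4, as were 13 of the 29 heat shock genes (fry, adjusted p = 0.0202; with an estimated correlation, camera gave adjusted p = 0.369). NEK10, PDK4, ABCA1, VSX1 and PER3 were higher, PER3 by a log2 fold change of 0.68 (adjusted p = 0.00919). For PER2 (-0.26, adjusted p = 0.145) and NFIL3 (-0.28, adjusted p = 0.130) the difference between the sets did not pass. Other scalings moved the split to 186 higher of 432 called, 185 of 451 and 232 of 430. Without lens library 14 the count was 9, and without 1, 2, 3, 12 or 13 it was 95, 268, 103, 170 or 165. The sets were not balanced for sex, with W-linked reads in 3 of libraries 1 to 4 and 1 of libraries 12 to 14. With the W-linked level as a covariate the count was 1446. DNAJA1 and NFIL3 lie on the sex chromosome Z.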

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

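All tests of explanations in this part were chosen after the result they bear on was seen, apart from the thinning of depth and the counts of other splits of the libraries.

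Within-group spread was examined for each named gene and for 5 measures per library, in 172 groups of 7 libraries, of which 9 held a library far from the others where chance alone flags about 5% of groups. Control 10 was the far library in 5: HSP90AA1 stood at 374 CPM, HSPA8 at 375 CPM against 496 to 558 CPM in the other controls, the ribosomal protein gene RPS19 at 5.56 CPM against 15.3 to 18.8 CPM, IRS2 at 45.7 CPM against 35.3 to 39.2 CPM, and GRIK1 at 130.1 CPM against 148 to 158 CPM. In lens libraries 1 to 4, HSP90AA1, HSPA8, RPS19 and GRIK1 were lower and IRS2 was higher than in control. Control 21 stood apart for SORBS2 (165 CPM) and RGS7 (83.0 CPM), control 19 for CRY4 (10.7 CPM), and lens library 12 for TMEM215 (2.54 CPM).

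The difference between the lens sets was itself past the threshold at 551 genes, and lens libraries 1 to 4 stood apart from controls at 1480 genes. Counts over other splits argue against chance for both, but the splits are too few to exclude it. Of 100 of the 330 splits of those libraries, 1 (the real split) gave as many as 1480 genes, the next calling 12. Of all 35 splits of the lens libraries 1 gave as many as 551, the next calling 290 and parting the libraries by their W-linked reads. With 35 splits no result can be rarer than 1 of 35. The tables argue against sex as the cause of the 1480 calls, since 1522 genes were called with the W-linked level as a covariate. Between the lens sets, which were not balanced for sex, that covariate moved the count from 551 to 1446. The tables also argue against depth for the 1480 calls, since 1341 were called with every library thinned to the lowest depth. The thinning rounded each value to whole steps, an approximation because not all low values were whole. For the genes that fell, they argue against dilution by other tissue. The median log2 fold change over 115 retinal cell type markers was 0.033 (95% bootstrap interval -0.029 to 0.086), so these markers did not fall together. The 446 genes called lower had a median of -0.34, but they were picked for being lower, so that value is no separate evidence. Other tissue as a source of genes that rose stays open: all 5 tested vascular and connective tissue markers were above 0, with a fry adjusted p of 0.115 against control and 0.0217 against lens libraries 12 to 14 (0.977 by camera with an estimated correlation), and the markers are too few to decide. RNA composition stays open as well: with the share of noncoding RNA as a covariate the count of 1480 fell to 122. All 1480 genes kept their direction and a median of 0.985 of their log2 fold change, but their SE grew by a median factor of 1.45, since the share itself differed between the sets; HSP90AA1 went from -1.05 (SE 0.13) to -0.97 (SE 0.18, adjusted p = 0.0349). Shared day, time or handling cannot be told apart from a lens response in libraries 1 to 4, as no dates are given. Lens wear alone is argued against for 467 of the 1480 genes, which were among the 551 that separated libraries of the same treatment. The count of 551 fell to 9 without lens library 14. For the other called genes lens wear alone stays open. Left out of the controls, control 10 showed 36.5% and control 21 showed 24.1% of the difference. The other 5 controls showed -6.12% to 8.83%, so that untreated retinas may carry part of the same shift.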

How the results depend on the processing

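No gene named by the fixed rule in a comparison with control changed direction under any alternative run for that gene; for the lens sets compared with each other, only the counts were recomputed. For these genes in lens libraries 1 to 4 against control, 1429 of 1613 checks kept their side of the threshold, 166 lost it and 18 gained it; in lens libraries 12 to 14, 282 of 286 kept it and 4 gained it, and in the pooled comparison 305 of 356 kept it and 51 gained it. The clock list kept its mixed call in the pooled comparison throughout (adjusted p 5.26e-07 to 0.00359). The cause of the changes below was not tested, except where the setting itself changes the libraries, the threshold or the smallest p possible. No paired analysis was possible because the groups share no replicate numbers. Both planned count models were not run, since whole reads could not be recovered for enough values.

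The pooled count of 0 genes became 16 with library weights, 28 at an adjusted p under 0.1, 1480 with lens libraries 1 to 4 only, and, with alternatives chosen after seeing the data, 78 with the 3 title-number sets fitted together and 136 with the W-linked level added. It ranged from 0 to 15 with 1 library left out (15 without lens library 14, 3 without 12 or 13, 2 without 4). Gene lists went from 0 to 1 with lens libraries 1 to 4 only and to 3 with camera at a correlation of 0.01. The count of 5 fixed genes past the list-alone threshold became 1 with no filter or with lens libraries 12 to 14 only and 3 with the title letter or the W-linked level as a covariate, and ranged from 1 to 5 with 1 library left out (1 without control 18, 19 or 21 or lens library 1, 2, 3 or 4, 2 without lens library 14, 3 without control 22 or 23 or lens library 12 or 13).

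The 1480 genes of lens libraries 1 to 4 against control became 2408 at an adjusted p under 0.1, 145 at 1.5-fold, 0 by exact rank-sum tests (smallest p possible 0.00606) and 122 with the share of noncoding RNA as a covariate, chosen after seeing the data, and ranged from 724 to 1636 with 1 library left out. The 0 genes of lens libraries 12 to 14 against control became 1 with library weights and 2 with the 3 sets and the W-linked level fitted together, and ranged from 0 to 2, with 2 without control 19. The 551 genes between the lens sets became 261 with no filter, 1239 with library weights, 278 with the title letter and 1446 with the W-linked level as a covariate, 1288 at an adjusted p under 0.1, 136 at 1.5-fold, 0 by rank-sum tests (smallest p possible 0.0571), 906 with the 3 sets fitted together and 1072 with the W-linked level added, and ranged from 9 to 807. Depth limits low genes: at the filter of 1 CPM a gene rests on about 27.7 to 49.3 reads per library.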

Other observations

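Beyond the groups described so far, 2 of 22 tested retinoid genes were called in lens libraries 1 to 4, where 1480 of 11005 genes were called in all. Both were higher (fry for the list, adjusted p = 0.616). The retinaldehyde reductase DHRS3 rose from 9.02 ± 1.14 to 14.5 ± 3.26 CPM (limma, adjusted p = 0.00728) and the retinoid X receptor RXRA from 3.02 ± 0.825 to 4.98 ± 1.37 CPM (adjusted p = 0.0372). RBP4, the retinol carrier, was at 237 ± 21.2 CPM in lens libraries 1 to 4 and 163 ± 17 CPM in lens libraries 12 to 14, a difference past the threshold (adjusted p = 0.0147). The cone genes GUCA1C (203 ± 18.4 to 159 ± 12.9 CPM) and KCNV2 (18.1 ± 2.64 to 11.7 ± 1.03 CPM) fell in libraries 1 to 4. These were 2 of 17 tested in the cone list, near the share called over all genes.

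The thyroid hormone deiodinase DIO2, listed as a Mueller glia marker, fell from 80.6 ± 9.01 to 57.3 ± 2.98 CPM in libraries 1 to 4 (adjusted p = 0.00276) and averaged 80.6 ± 3.42 CPM in libraries 12 to 14. ID4, a target of BMP signalling, fell from 4.64 ± 1.01 to 2.37 ± 0.625 CPM (adjusted p = 0.00754). All 5 tested vascular and connective tissue markers were higher in libraries 1 to 4 than in libraries 12 to 14 (fry, adjusted p = 0.0217; camera with an estimated correlation, adjusted p = 0.977), with COL6A1 at 6.14 ± 1.03 and 3.27 ± 0.638 CPM.

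A hypothesis is that clock genes were altered in lens retinas of both sets. Tests of explanations for it were chosen after the result was seen, apart from the count of splits. The mixed test ignores direction, and the members did not all move alike in libraries 1 to 4 and 12 to 14. PER2, NFIL3 and ARNTL (log2 fold change 0.64 and 0.59) kept their direction. PER3 (0.05 and -0.62), NPAS2 (0.27 and -0.14) and BHLHE40 (0.26 and -0.30) did not. Of 100 of the 1716 splits of the 14 libraries, 1 (the real split) gave the clock list an unadjusted mixed p as small as 7.8e-06, the next being 0.000417. That argues against chance but cannot exclude it, since 100 splits were counted and 1 of the 35 tested lists was examined in this way. Sex is argued against by a mixed-test adjusted p of 1.4e-05 with the W-linked level as a covariate. Libraries 12 to 14 alone gave a mixed-test adjusted p of 0.00140, which argues against libraries 1 to 4 as the sole carriers of any change in the list. It does not show that both sets carry the same change, since the test ignores direction and the controls were shared. No splits were counted for the clock list in libraries 12 to 14. Collection of the groups at different times of day cannot be told apart from an effect of the lens, because no times are given, and clock genes also differed between lens sets of the same treatment (adjusted p = 0.000147), which may reflect such a difference.

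For the pooled comparison chance is not excluded: of 100 of the 1716 splits, 7 gave as many as the 1619 genes at an unadjusted p under 0.05 (highest other 2231). The counts of 0 called genes and 0 gene lists cannot be tested this way, since every split gives at least 0 (100 of 100 for both; the highest others were 501 genes and 3 lists), and were counted after they were seen. The split with 501 calls parted the libraries fully by their W-linked reads, a structure of the samples. For lens libraries 12 to 14 against control chance is not excluded either: of 100 of 120 splits, 35 gave as many as the 571 genes at an unadjusted p under 0.05 (highest other 1466), a test chosen after the result was seen. The count of 0 called genes again allows no test (100 of 100); the highest other was 151, with the largest difference in W-linked reads that this design allows.

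The lens sets share their controls, so overlap between them is above chance with no effect. At an unadjusted p under 0.05, 76 genes were higher and 102 lower in both, against 35.5 and 35.7 in simulated unchanged groups and 49.1 and 33.4 for independent lists, with 36 genes in opposite directions against 3.75 in the simulated groups. The simulated groups carried no change in either set, while libraries 1 to 4 had 3328 genes at that p against control. The simulated overlaps are therefore not those to expect for lists of the observed length. The controls were also split, 4 for libraries 1 to 4 and 3 for libraries 12 to 14. Then 39 were higher and 93 lower in both and 188 went in opposite directions, against 43.6, 60.9 and 182 for independent lists. The genes higher in both were thus fewer than that. This split cannot decide on a shared effect, because sex was unbalanced in opposite ways. Lens libraries 1, 2 and 3 held W-linked reads, but of controls 10, 17, 18 and 19 only 19 did. Lens library 13 held them among libraries 12 to 14, and controls 21 and 23 among controls 21, 22 and 23. With the 3 sets fitted together, chosen after seeing the data, the average of both lens effects called PER2 (log2 fold change -0.41, adjusted p = 0.0165), NFIL3 (0.50, adjusted p = 0.0149), REEP2 (0.33), COL9A3 (0.60), GRM5 (-0.33) and XIAP (-0.30), among 78 genes. Such an average can rest on 1 set: HSP90AA1 was also called, at -1.05 in libraries 1 to 4 and 0.02 in libraries 12 to 14.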
